A study of Mus musculus with 12 samples.

How the data were processed

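The measurements were made on Affymetrix 430A mouse expression arrays, per the labels. Each of 12 arrays received biotin-labelled RNA from the scraped epithelial layer of the colon. Per the labels, RNA of 3 different mice was pooled for each array, and 3 arrays were made for each of 4 groups, so a group holds 9 mice. Mice in different groups were separate animals per the design text. A replicate is therefore a pool, and the spread between replicates is the spread between pools plus that of the laboratory steps.

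The submitters' processing notes name MAS5 and RMA without a version and without saying which of the pair made the deposited table. The roles of these methods are not given in the sources used here. The deposited values were taken to be log2 signal. They ran from 2.7 to 14.09 with 2 decimals, and the top lies above 11.1, the natural logarithm of the largest count of a 16-bit scanner, so they are not natural logarithms. No background correction, summary of probes or normalization was repeated, and the deposited table was used as it stands. Raw image files were not used here.

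The table held 22690 probe sets. The 64 Affymetrix control probe sets were left out of the tests, so that 22626 were tested, and no filter on signal was set. Gene names came from the array annotation supplied with the reference. Of the tested probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had no name, and the named ones stood for 12393 genes. By gene identifier 20351 were found in the mouse RefSeq gene table of GRCm38.p6, and 0 symbols had to be changed. The assembly served only for names and for finding neighbouring genes. The gene deleted in the null line is not analysed here.

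Group means were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with trend=TRUE. All 12 arrays entered 1 fit with 4 group means and 7 contrasts. The contrasts were quercetin in each genotype, genotype on each diet, their interaction and both averages. The fit had 8 residual degrees of freedom and a prior of 4.91, which gave moderated tests with 12.91 degrees of freedom. All tests were two-sided, and p was adjusted by Benjamini and Hochberg over the tested probe sets of a contrast with a threshold of 0.05. Standard errors (SE) are those of the moderated fit unless a paragraph says otherwise, and SD is the spread over 3 arrays. The labels give no litter, day or batch for a replicate number. No pairing entered the fit.

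Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, with 1 probe set per gene, the one of the highest mean. All 40 lists had at least 3 measured genes, and p was adjusted over the lists of a contrast. The same lists were tested with camera at a correlation estimated for each list, and with fry, which rotates the residuals and so takes account of the correlation between genes. A preset correlation of 0.01 is far below that of the cell type lists in these arrays, for instance 0.79 for the smooth muscle genes, so that its small p values treat genes that move together as nearly independent. The text therefore gives the p with an estimated correlation beside each list. Numbers of list members past the threshold are given with p adjusted over all probe sets and with p adjusted over the list alone.

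The grouping, the 7 contrasts, the tests, the 40 lists, the threshold, the rule for named genes and most alternatives were fixed before the data were examined. Some choices were made after values were seen, namely leaving out 3 arrays with pancreatic signal, list means as covariates for tissue mix, exact permutation of list means, and a comparison of genes called with single arrays left out. The rules for 3 explanations were also replaced after their values were known. For a uniform loss of epithelial cells, smooth muscle genes were first set against endothelial, neuron and glia genes, which left the matter open as low signal could hide a rise, and were then set against fibroblast and matrix genes. With a standard error over genes this argued against a loss, but the genes move together, and with one over arrays the matter was left open again. For the cholesterol synthesis genes, leaving out wild type control arrays 2 and 3, which had been picked for their low means, gave way to the difference on the quercetin diet. For the genes near Ccn3 the rule was made stricter, and the explanation, first argued against, was left open. Recovery of simulated changes with the tissue mix covariates was added last, with its rule written before it was run. Named genes are those past the threshold without overlap between groups, or, where fewer than 10 pass, the 10 of the smallest unadjusted p, or 5 for the interaction and the quercetin average. Only probe sets with 1 gene symbol were eligible, so that some with several names or none had a smaller p and were passed over. Up to 5 members of the smallest unadjusted p are named for a list, and Cyp1a1, Cyp1b1 and Nqo1 were fixed for both quercetin contrasts. For a gene with several probe sets, the one of the smallest p stands for genes of the first kind and the one of the highest mean for list members.

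The fit was checked on simulated data made for the quercetin contrast in wild type, with changes put into 200 of 22626 probe sets in each of 5 runs. Of 250 probe sets at each size, 70.8% were recovered at 1.5-fold, 98% at 2-fold and 100% at 4-fold and at 8-fold. There were 51 false calls over the runs. The later recovery test gave 93.2% at 2-fold for this contrast without covariates. These shares hold for 200 probe sets changed together, as the adjustment is stricter when fewer change. In the real arrays Ccn3 was 6.22-fold lower in wild type mice on quercetin and did not pass. A count of 0 therefore does not exclude large changes in single genes. A gene list shifted by 0.5 log2 units was called in 5 of 5 runs, and 0 of 195 tests of other lists passed. Genes were simulated as independent, whereas those of real lists move together, so this 0 is no measure of false calls in these arrays. With 3 against 3 arrays an exact permutation test cannot go below p = 0.1, and 10% of unchanged probe sets are expected to show no overlap between groups. Figures were drawn with matplotlib 3.10.9, with tables read by pandas 2.3.3, in Python 3.11.15.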

Results

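A set of 12 arrays described the colon epithelium of male wild type and POR-null mice on a control diet or on a diet with quercetin. Quercetin is a flavonol of plants, and POR is the reductase that passes electrons to microsomal cytochromes P450 and to squalene epoxidase. Per the labels the mice had 14 days on a soya-free powder, then 24 hours on the same powder with or without 6200 ppm quercetin, about 7 mg for each mouse. The null line deletes the gene in hepatocytes, as known from the literature, so its colon is expected to keep the gene while the liver lacks it. The design asks what quercetin does in each genotype, how the genotypes differ on each diet, and whether the response to quercetin depends on the genotype.

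Array medians ran from 5.9 to 5.98 log2 units, and correlations between arrays were as high between groups (median 0.989, from 0.981 to 0.993) as within groups (median 0.989, from 0.984 to 0.995). The first principal component carried 23.7% of the variance and the second 14.5%. The first set wild type control arrays 2 and 3, at 24.7 and 24.9, against POR-null control array 1 at -24.2. The first wild type control array lay at -3.1, so the groups were not parted by this component. Differences between 3 prime and 5 prime control probe sets ran from 0.97 to 1.29 for actin and from -0.05 to 0.17 for Gapdh. Goblet cell genes averaged 10.8 to 10.89 and absorptive colonocyte genes 11.29 to 11.39 in the 4 groups (n = 3 arrays each), and neither list passed in any contrast.

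In wild type mice on quercetin, Ccn3, a secreted matrix protein of the CCN family, had a mean of 4.54 (SD 0.88) against 7.17 (SD 0.27) on control diet, a log2 difference of -2.64 (SE 0.36, n = 3 arrays per group). Deptor, a binding protein that inhibits mTOR, stood at 8.42 against 9.12 (-0.70, SE 0.12). Gas5, a host transcript of small nucleolar RNAs, stood at 9.05 against 8.27 (0.78, SE 0.14), and Plbd1, a phospholipase B-like protein, at 8.26 against 7.52 (0.74, SE 0.15). The copper chaperone Sco2 differed by -0.58, the ER retrieval receptor Kdelr2 by -0.53 and the phosphatase Bpnt1 by -0.60. Ccdc91 differed by -0.50, Rsrc1 by 0.29 and Zbtb16 by 0.33. These lay at low signal, with control means of 4.48, 3.62 and 3.35, below the lower quartile of every array (4.65 at the lowest). By limma 0 of 22626 probe sets passed the adjusted threshold, with the smallest adjusted p = 0.119 for Ccn3, 0.492 for Deptor and Gas5, and at most 0.851 for the other 7 genes. At an unadjusted p under 0.05 there were 1165 (5.15%, 725 higher and 440 lower), and 2106 (9.31%) had no overlap between groups where 10% would be expected by chance. A second Ccn3 probe set differed by -2.69, whereas the other Deptor probe sets differed by -0.27 and -0.23 and those of Bpnt1 and Ccdc91 by -0.20 each and of Zbtb16 by -0.05. Without wild type quercetin array 1 Ccn3 passed (-3.10, adjusted p = 0.00264), and with array weights it passed as well (-2.66, adjusted p = 0.0195). Array 1 had the highest Ccn3 of the quercetin arrays (5.47 against 4.42 and 3.72), so leaving it out enlarged the difference. Ccn3 did not pass with any other single array left out.

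Genes that respond to ligands of the aryl hydrocarbon receptor gave no difference past the threshold after quercetin in wild type mice. The P450 enzymes Cyp1a1 (6.01 against 5.97, difference 0.04, SE 0.12) and Cyp1b1 (0.15, SE 0.16) and the quinone reductase Nqo1 (-0.43, SE 0.23) had adjusted p of 0.991, 0.966 and 0.957 by limma (n = 3 arrays per group). The receptor's target list had a median of -0.08 (camera adjusted p = 0.127) and the 35 P450 genes one of -0.04 (adjusted p = 0.135). Within the latter, Cyp3a11, a xenobiotic oxidase, averaged 7.11 (SD 1.45) against 9.12 (SD 0.51), a difference of -2.02 (SE 0.71). Of the 35 conjugating enzymes 28 were lower (median -0.16), led by the glutathione transferases Gstm3 (-0.42, SE 0.13) and Gsta4 (-0.56, SE 0.21). Of the 25 NRF2 antioxidant targets 20 were lower (median -0.15), with Txnrd1 at -0.32 (SE 0.12), while the epoxide hydrolase Ephx1 was higher by 0.45 (SE 0.11). By camera the adjusted p was 1.9e-05 for the conjugating enzymes and 0.00272 for the NRF2 targets, and 0.463 for both with an estimated correlation. With p adjusted over all genes 0 members of these lists passed, and over the list alone 0 conjugating enzymes and 1 NRF2 target. That target was Ephx1, which was higher and so went against the direction of its list. The medians were -0.10 for the conjugating enzymes without wild type control array 2 and -0.07 for the NRF2 targets without wild type quercetin array 1, and the NRF2 call was lost without wild type control array 2. These lists moved in arrays in which smooth muscle and immune genes also differed, as the next values show.

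Smooth muscle genes were the furthest apart in this contrast, with all 16 higher on quercetin and a median of 1.47. Myl9, a myosin light chain, was higher by 2.76 (SE 0.77), the actin binding Tagln by 2.60 (SE 0.78), enteric actin Actg2 by 2.97 (SE 0.91) and Acta2 by 1.96 (SE 0.64), n = 3 arrays per group. The 3 wild type quercetin arrays had list means of 6.32, 7.43 and 9.07, and the control arrays 6.19, 6.04 and 6.00. For this list camera gave an adjusted p = 6.07e-14, and 0.463 with an estimated correlation; 12 genes passed over the list alone and 0 over all genes. Without wild type quercetin array 3 the median was 0.74, and without array 1 it was 2.06. Fibroblast and matrix genes were higher in 22 of 22 cases (median 0.61), for instance Dpt by 1.33 (SE 0.39) and Postn by 1.41 (SE 0.46). Their camera adjusted p was 4.95e-10, and 0.463 with an estimated correlation, with 0 genes passing either way, and the median was 0.36 without wild type quercetin array 3 and 0.93 without wild type control array 1. The 14 endothelial genes had a median of 0.14 (camera adjusted p = 0.00168, and 0.463 with an estimated correlation). Tissue mix covariates, chosen after values were seen, turned the direction by camera of the fibroblast and endothelial lists.

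Immune genes were also higher in wild type mice on quercetin. Of 10 MHC class II presentation genes 9 were higher (median 0.92), among them the invariant chain Cd74 by 1.74 (SE 0.50), H2-Ab1 by 1.46 (SE 0.43) and H2-Eb1 by 1.62 (SE 0.48), n = 3 arrays per group. Of 18 B and plasma cell genes 16 were higher (median 0.48), with the B cell receptor subunit Cd79b at 1.52 (SE 0.60) and Cd22 at 0.69 (SE 0.26). Macrophage and dendritic cell genes had a median of 0.23 and T and NK cell genes one of 0.17. For these 4 lists camera gave adjusted p of 1.15e-07, 7.32e-06, 1.22e-04 and 1.65e-04 in this order, and 0.463 for each with an estimated correlation. Over the list alone 5 MHC class II genes and 0 genes of the other 3 lists passed, and 0 over all genes. Without wild type control array 1 the B and plasma cell median was 0.81, without wild type control array 2 the macrophage median was 0.15, and without wild type quercetin array 1 the T and NK cell median was 0.26. In the 3 control arrays the MHC class II means were 8.07, 7.09 and 6.98, so that array 1 resembled the quercetin arrays at 7.76, 8.42 and 8.70.

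A further 7 lists passed with the preset correlation in wild type mice, and each lost the call when some single array was left out. Fatty acid oxidation genes had a median of -0.12 (34 genes, limma camera adjusted p = 2.6e-04, and 0.526 with an estimated correlation, lost without wild type control array 2) and oxidative phosphorylation genes -0.06 (57 genes, 0.00444, and 0.723, lost without wild type control array 2 or 3). Heat shock genes had -0.20 (18 genes, limma camera adjusted p = 0.00368, and 0.526 with an estimated correlation), with Hspa1b at -0.99 (SE 0.37) and Hspb1 at 0.75 (SE 0.27), and the call was lost without wild type control array 2 or quercetin array 1. Endoplasmic reticulum stress genes had -0.11 (24 genes, limma camera adjusted p = 0.00444, and 0.526 with an estimated correlation, lost without wild type control array 1 or quercetin array 3), and ion and water transport genes -0.13 (22 genes, 0.0175, and 0.526, lost without wild type control array 3 or quercetin array 3). Small intestine genes had -0.51 (17 genes, limma camera adjusted p = 5.18e-04, and 0.526 with an estimated correlation), with the glucose carrier Slc5a1 at -0.37 (SE 0.12), lost without wild type control array 1 or quercetin array 1. Pancreatic acinar genes had -0.98 (14 genes, limma camera adjusted p = 8.76e-04, and 0.585 with an estimated correlation), with Reg1 at -1.79 (SE 0.62), and the median was -0.24 and the call lost without wild type control array 1. None of the members of these lists passed over all genes or over the list alone. In all, 16 of 40 lists passed in this contrast (7 higher, 9 lower) with the preset correlation, and 0 with an estimated correlation or by fry (smallest adjusted p = 0.501).

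**Figure D1:**
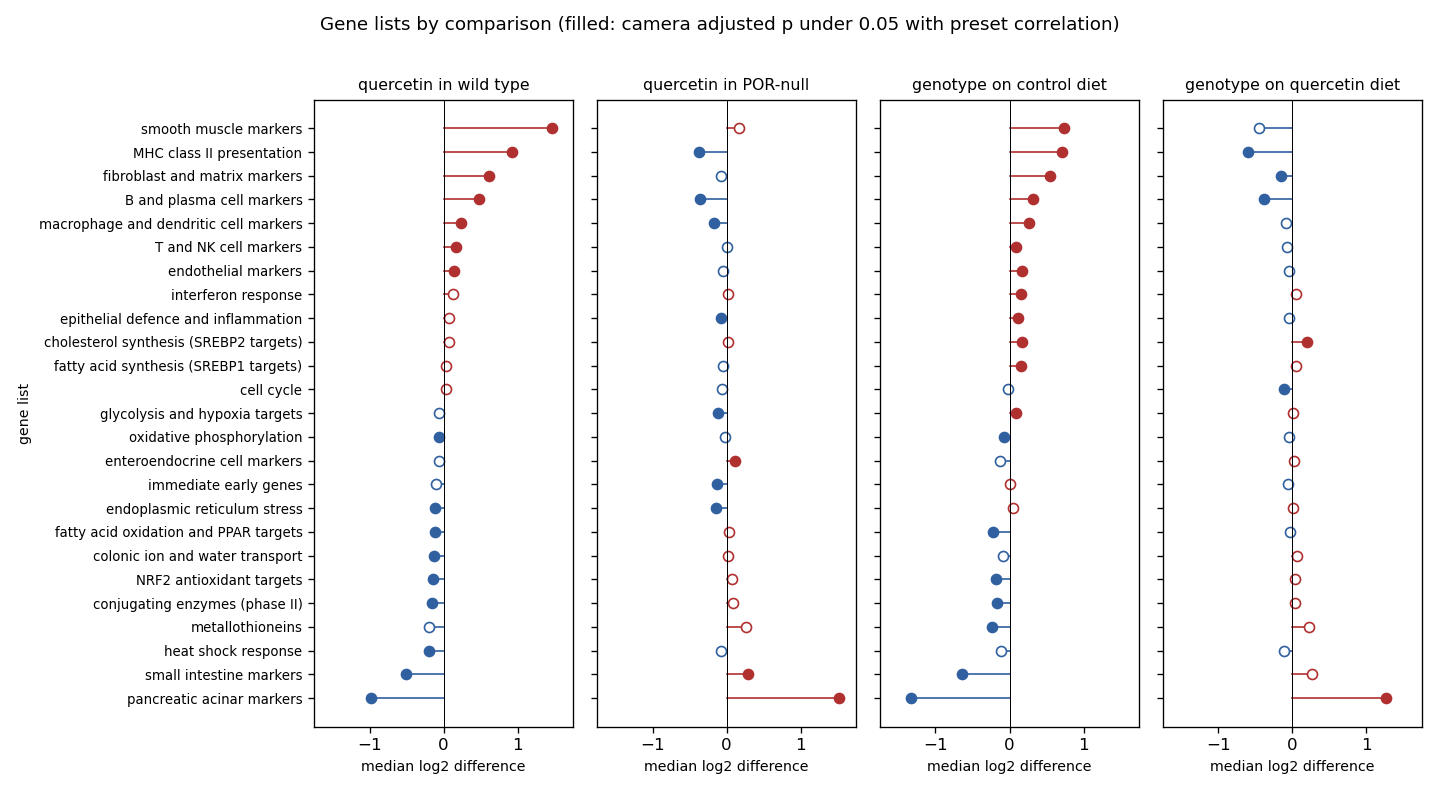
Median log2 difference of the gene lists that passed in at least 1 of the 4 simple comparisons, with smooth muscle genes at 1.47 for quercetin in wild type and 0.17 in POR-null mice. Filled points passed with camera at the preset correlation of 0.01, and 0 lists passed with an estimated correlation.

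In POR-null mice on quercetin the smallest p among probe sets with 1 gene symbol belonged to Sorl1, a sorting receptor, at 8.81 against 9.41 (-0.60, SE 0.13, n = 3 arrays per group). Btg2, an antiproliferative early response gene, stood at 8.51 against 8.99 (-0.48, SE 0.11), the syndecan Sdc4 at 7.34 against 8.91 (-1.58, SE 0.40), the epithelial transcription factor Elf3 at 10.15 against 10.54 (-0.39, SE 0.10) and the growth factor receptor Egfr at 5.68 against 6.06 (-0.38, SE 0.10). Marcksl1 differed by -0.46, Gna13 by -0.45, Ccdc93 by -0.30, Zfp787 by 0.34 and Hnrnpdl by 0.45. Signal was low for Marcksl1, Ccdc93 and Hnrnpdl, with control means of 4.51, 4.23 and 3.49. The xenobiotic response genes Cyp1a1 (0.00, SE 0.12), Cyp1b1 (-0.33, SE 0.16) and Nqo1 (0.16, SE 0.23) gave no difference past the threshold. No gene passed by limma, 0 of 22626 probe sets (adjusted p = 1 for each named gene), with 637 (2.82%) at an unadjusted p under 0.05 and 1528 (6.75%) without overlap, where 10% would be expected by chance. Other probe sets gave 0.09 for Sdc4, -0.07 for Sorl1, -0.50 to -0.13 for Marcksl1, -0.09 for Ccdc93 and 0.09 for the brightest of Egfr, and at least 1 of them had the opposite sign for Gna13, Zfp787, Hnrnpdl and Cyp1b1. Gbp2b, an interferon-induced GTPase chosen after values were seen, stood at 7.47 and 7.86 in POR-null quercetin arrays 2 and 3 and between 4.96 and 5.33 in the other 10 arrays. It passed only without POR-null quercetin array 1 (2.55, adjusted p = 9.92e-06), then also in the interaction (2.53, adjusted p = 3.1e-04) and in both averages. The labels give no genetic background for single pools, and whether such a difference lies behind this gene was not tested.

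Of 20 glycolysis and hypoxia genes 19 were lower on quercetin in POR-null mice (median -0.12), among them the prolyl hydroxylase Egln3 by -0.57 (SE 0.20), hexokinase Hk2 by -0.40 (SE 0.16) and Bnip3 by -0.40 (SE 0.16), n = 3 arrays per group. Of 20 immediate early genes 14 were lower (median -0.13), with the stress factor Atf3 at -0.44 (SE 0.12) and the survival factor Mcl1 at -0.45 (SE 0.15). Of 24 endoplasmic reticulum stress genes 22 were lower (median -0.15). Camera gave adjusted p of 2.89e-07, 8.66e-05 and 1.09e-05, and 0.432, 0.539 and 0.609 with an estimated correlation. Over the list alone 0, 2 and 0 of these genes passed, and 0 over all genes. The arrays of both groups did not overlap in the means of the first pair of lists, and no call was lost with any array left out. The medians were -0.20 without POR-null control array 1, -0.08 without POR-null control array 2 and -0.25 without POR-null control array 3 for the lists in that order. In the same arrays the B and plasma cell genes (median -0.37) and the acinar genes (median 1.51) also differed.

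Acinar genes were higher on quercetin in POR-null mice in 12 of 14 cases, with the carboxypeptidase Cpb1 at 2.38 (SE 1.01), Reg1 at 1.44 (SE 0.62) and the elastase Cela3b at 2.19 (SE 0.96), n = 3 arrays per group. Array 2 had a list mean of 9.60, and arrays 1 and 3 had 6.81 and 6.64, against 6.38, 6.43 and 6.26 on control diet. The camera adjusted p was 2.89e-07, and 0.609 with an estimated correlation; without array 2 the median was 0.52. B and plasma cell genes were lower in 16 of 18 cases (median -0.37, adjusted p = 8.66e-05, and 0.609 with an estimated correlation), macrophage genes had a median of -0.17 (adjusted p = 3.87e-04, and 0.609) and MHC class II genes -0.38 (adjusted p = 0.00855, and 0.664). All 3 calls were lost without POR-null control array 1, where the medians were -0.13, -0.09 and -0.16. Small intestine genes had 0.29 (adjusted p = 0.00992, and 0.776 with an estimated correlation), epithelial defence genes -0.08 (0.0148, and 0.609) and enteroendocrine genes 0.11 (0.0291, and 0.609). The small intestine call was lost without POR-null control array 2 or 3 or quercetin array 2, the defence call without control array 3 or quercetin array 3, and the enteroendocrine call without control array 1 or any quercetin array. Altogether 10 of 40 lists passed (3 higher, 7 lower), and 0 with an estimated correlation or by fry (smallest adjusted p = 0.699).

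On control diet, POR-null mice differed from wild type mice by 0.43 (SE 0.08) in Dync1h1, the dynein heavy chain, with means of 9.36 and 8.93 (n = 3 arrays per group). Mpst, a mitochondrial enzyme that makes hydrogen sulfide, stood at 6.95 against 7.99 (-1.04, SE 0.20), Gas5 at 8.98 against 8.27 (0.71, SE 0.14), and Klf7, a Krüppel-like factor, at 6.80 against 6.10 (0.70, SE 0.15). The fatty acid transporter Slc27a2 differed by -0.65 (SE 0.15) and the aminopeptidase Xpnpep2 by -0.85 (SE 0.19). Lgalsl differed by 0.61, Ypel5 by 0.47, Rraga by -0.44 and Lats2 by -0.34, the last at low signal with a wild type mean of 4.35. Other probe sets ran from -0.27 to 0.14 for Lats2 and from 0.02 to 0.17 for Klf7 and gave 0.23 for Lgalsl. By limma 0 of 22626 probe sets passed (adjusted p = 0.71 for these 10 genes and 0.545 at the smallest), with 1537 (6.79%, 833 higher and 704 lower) at an unadjusted p under 0.05 and 2187 (9.67%) without overlap, where 10% would be expected by chance. With array weights 399 probe sets passed, among them Dync1h1 (0.51) and Mpst (-1.42), both at adjusted p = 0.0261. The highest weights were 2.49 for wild type control array 3 and 2.72 for POR-null control array 2. Without wild type control array 1 there were 41, among them the sulfate donor enzyme Papss2 (adjusted p = 0.0108), the bile acid carrier Slc10a2 (-1.72, adjusted p = 0.0165), Hmgcs1 (1.12, adjusted p = 0.0166) and Fdft1 (1.08, adjusted p = 0.0318), genes named here after values were seen.

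Of 19 cholesterol synthesis genes 18 were higher in POR-null mice on control diet (median 0.17), with HMG-CoA synthase Hmgcs1 at 0.76 (SE 0.23), squalene synthase Fdft1 at 0.58 (SE 0.21), Msmo1 at 0.52 (SE 0.19), Idi1 at 0.58 (SE 0.23) and Mvd at 0.39 (SE 0.16), n = 3 arrays per group. Of 19 fatty acid synthesis genes 13 were higher (median 0.15), with the desaturases Scd1 at 1.63 (SE 0.45) and Scd2 at 0.83 (SE 0.24) and Fasn at 0.31 (SE 0.13). Their camera adjusted p were 1.21e-06 and 0.00101, and 0.431 and 0.428 with an estimated correlation. Over the list alone 0 cholesterol and 2 fatty acid synthesis genes passed, and 0 over all genes. Without POR-null control array 3 the medians were 0.29 and 0.24, and without array 1 the fatty acid synthesis median was 0.08. Fatty acid oxidation genes were lower in 30 of 34 cases (median -0.22, adjusted p = 7.29e-06, and 0.459 with an estimated correlation), and their call was lost without wild type control array 2, where the median was -0.11. Smooth muscle, fibroblast and MHC class II genes were higher in the same contrast.

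Conjugating enzymes were lower in POR-null mice on control diet in 29 of 35 cases (median -0.17), and Gstm3 differed by -0.46 (SE 0.13) and Gsta4 by -0.61 (SE 0.21), n = 3 arrays per group. The list means of both groups only just did not overlap (10% by chance), with wild type control array 1 at 7.842 and POR-null control array 1 at 7.840. NRF2 targets were lower in 20 of 25 cases (median -0.18), with the carbonyl reductase Cbr3 at -1.17 (SE 0.28) and Nqo1 at -0.62 (SE 0.23). Adjusted p by camera were 7.29e-06 and 1.55e-04, and 0.428 and 0.431 with an estimated correlation; over the list alone 0 conjugating enzymes and 2 NRF2 targets passed, and 0 over all genes. The 4 metallothioneins had a median of -0.23 (adjusted p = 0.0429, and 0.431), lost without wild type control array 2 or 3 or POR-null control array 1 or 3. Smooth muscle genes were higher in 16 of 16 cases (median 0.74, adjusted p = 7.29e-06, and 0.486 with an estimated correlation), fibroblast genes in 19 of 22 (0.54, 5.18e-06, and 0.459) and MHC class II genes in 10 of 10 (0.70, 4.01e-05, and 0.431). Macrophage genes had a median of 0.26 (1.21e-06, and 0.428), B and plasma cell genes 0.32 (8.78e-05, and 0.486) and endothelial genes 0.16 (0.00101, and 0.459), the last pair lost without POR-null control array 1. Without wild type control array 3 the fibroblast median was 0.23, and without wild type control array 1 the B and plasma cell median was 0.65. Tissue mix covariates, chosen after values were seen, turned the direction by camera of the fibroblast and endothelial lists here as well.

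Small intestine genes were lower in POR-null mice on control diet in 15 of 17 cases (median -0.65), with Slc5a1 at -0.44 (SE 0.12) and the lipoprotein Apob at -0.85 (SE 0.27), and 1 gene passed over the list alone (n = 3 arrays per group). Acinar genes had a median of -1.33 with 12 of 14 lower, while the lipase Pnliprp2 was higher by 2.69 (SE 0.93). Both lists passed by camera, with adjusted p of 4.73e-05 and 0.00101, and 0.459 and 0.574 with an estimated correlation. Without wild type control array 1 the medians were -0.35 and -0.67, and the acinar call was lost. Interferon response genes had 0.15 (p = 0.00157, and 0.574 with an estimated correlation), glycolysis genes 0.09 (0.00283, and 0.431), oxidative phosphorylation genes -0.08 (0.00283, and 0.574), epithelial defence genes 0.11 (0.00286, and 0.431) and T and NK cell genes 0.08 (0.0115, and 0.495). Each of these 5 calls was lost with some array left out, namely without POR-null control array 1 for the interferon and T cell lists, array 2 for glycolysis and array 3 for the other pair, with medians of 0.04 for interferon without wild type control array 3 and -0.01 for oxidative phosphorylation without POR-null control array 3. In all, 19 of 40 lists passed (12 higher, 7 lower), and 0 with an estimated correlation or by fry (smallest adjusted p = 0.434). The contrast shares its 3 wild type control arrays with the quercetin contrast in wild type mice, so that anything peculiar to those arrays enters both with the same sign.

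**Figure D2:**
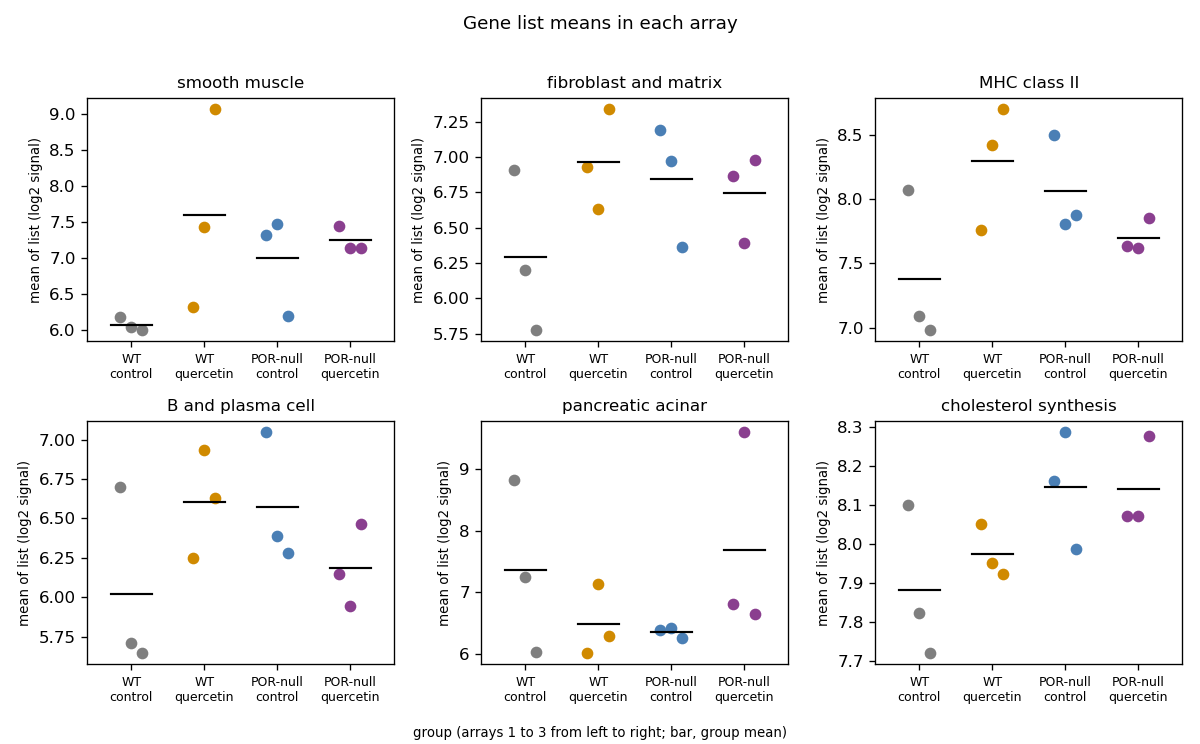
Means of 6 gene lists in each array, with wild type control arrays 2 and 3 lowest for B and plasma cell genes (5.71 and 5.65) and for cholesterol synthesis genes (7.82 and 7.72). The acinar mean was 9.60 in POR-null quercetin array 2 and 8.82 in wild type control array 1.

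On the quercetin diet, the smallest unadjusted p between genotypes belonged to Ccn3, with 6.46 (SD 0.44) in POR-null and 4.54 (SD 0.88) in wild type mice (1.92, SE 0.36, n = 3 arrays per group). Sdc4 had the larger difference, with 7.34 (SD 0.17) and 9.48 (SD 0.40) (-2.14, SE 0.40). Deptor differed by 0.65 (SE 0.12), the serine incorporator Serinc3 by 0.51 (SE 0.11), the sugar phosphate carrier Slc37a2 by -0.85 (SE 0.20) and Pm20d1, an enzyme of N-acyl amino acids, by 0.75 (SE 0.19). Zfp46 differed by -0.45, Zfp40 by -0.19, Clnk by -0.27 and Eny2 by -0.59. Signal was low for Zfp40 and Clnk, with wild type means of 3.13 and 3.77. The other probe sets went the opposite way for Sdc4 (0.28), lay between -0.04 and 0.06 for Eny2 and gave 0.22 and 0.05 for Deptor, 0.16 to 0.41 for Serinc3 and -0.07 for Zfp46. By limma 0 of 22626 probe sets passed (adjusted p = 0.926 for Ccn3, Sdc4 and Deptor and 0.998 for the other 7), with 541 (2.39%) at an unadjusted p under 0.05 and 1544 (6.82%) without overlap, where 10% would be expected by chance. Sdc4 passed when only the 6 arrays of the contrast were fitted (adjusted p = 0.0314). It also passed with the replicate number as a block (adjusted p = 0.0467), a pairing that the labels do not state. Ccn3 passed without wild type quercetin array 1 (2.39, adjusted p = 0.0439) and Gbp2b without POR-null quercetin array 1 (2.51, adjusted p = 1.21e-05). In each case the array left out was the one of its group closest to the other group.

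Cholesterol synthesis genes were higher in POR-null mice on the quercetin diet as well, in 17 of 19 cases (median 0.19, n = 3 arrays per group). Squalene epoxidase Sqle differed by 0.30 (SE 0.15) and Msmo1 by 0.37 (SE 0.19). The list means only just did not overlap (10% by chance). POR-null quercetin arrays 1 and 2 stood at 8.071 and wild type quercetin array 1 at 8.051. B and plasma cell genes were lower in 15 of 18 cases (median -0.38), with Cd79b at -1.43 (SE 0.60), and MHC class II genes in 9 of 10 (median -0.60), with H2-DMb2 at -0.60 (SE 0.21). Acinar genes were higher in 14 of 14 cases (median 1.26), a value of 0.22 without POR-null quercetin array 2, where the call was lost. The camera adjusted p were 1.52e-05, 7.7e-06, 2.07e-05 and 1.12e-07 in this order, and 0.848 for each with an estimated correlation, and 0 members passed over all genes or over the list alone. Without POR-null quercetin array 3 the cholesterol median was 0.11 and the B and plasma cell median -0.58. Cell cycle genes had a median of -0.11 (adjusted p = 0.0259) and fibroblast genes -0.15 (0.0452), both at 0.848 with an estimated correlation, and both calls were lost without wild type quercetin array 3. With tissue mix covariates, chosen after values were seen, the fibroblast median turned to 0.11 (camera adjusted p = 0.0185, and 0.86 with an estimated correlation). Altogether 6 of 40 lists passed (2 higher, 4 lower), and 0 with an estimated correlation or by fry (smallest adjusted p = 0.946).

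**Figure D3:**
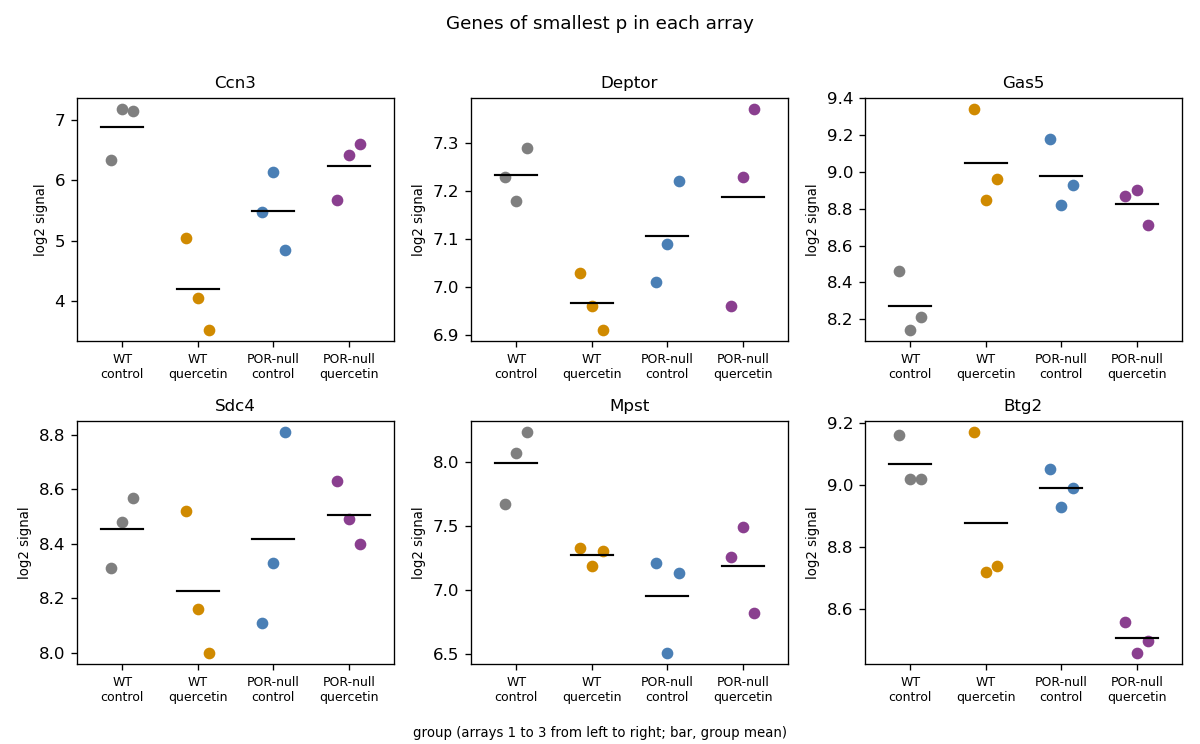
Signal of 6 genes in each array, none past the adjusted threshold. The panels of Ccn3, Deptor and Sdc4 show another probe set than the one of small p named in the text. The drawn Ccn3 probe set stood at 6.34, 7.18 and 7.15 in the wild type control arrays and 5.04, 4.04 and 3.51 in the quercetin arrays. The drawn Sdc4 probe set differed by 0.28 between genotypes on the quercetin diet, opposite to -2.14 in the named one.

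Averaged over both diets, POR-null mice differed from wild type mice by -0.33 (SE 0.07) in Rraga, a GTPase of amino acid sensing, and by 0.30 (SE 0.06) in Tradd, an adaptor of TNF receptor signalling, with 6 arrays per genotype. Ggps1 differed by 0.51 (SE 0.12) in 1 probe set and by -0.10, -0.13 and 0.07 in the other 3, Rhoc by 0.34, Ypel5 by 0.33, Klf7 by 0.44, Guca1a by 0.28, Eny2 by -0.44, Cenpo by -0.31 and Rtn4 by -0.45. Other probe sets lay between -0.01 and 0.01 for Klf7, -0.07 and 0.07 for Eny2 and -0.03 and 0.03 for Cenpo. The limma fit gave 0 of 22626 probe sets past the threshold (adjusted p = 0.997 for each), and 946 (4.18%) had an unadjusted p under 0.05. Cholesterol synthesis genes were higher in 17 of 19 cases (median 0.15), with Msmo1 at 0.44 (SE 0.14), Hmgcs1 at 0.53 (SE 0.17), Sqle at 0.33 (SE 0.11), Fdft1 at 0.43 (SE 0.15) and Idi1 at 0.46 (SE 0.16). Fatty acid synthesis genes had a median of 0.095 with 14 of 19 higher, Scd2 at 0.65 (SE 0.17), Scd1 at 0.84 (SE 0.32) and Fasn at 0.27 (SE 0.09). The camera adjusted p were 2.49e-11 and 4.3e-04, and 0.343 and 0.277 with an estimated correlation; over the list alone 0 and 1 genes passed, and 0 over all genes. Neither call was lost with any array left out, and the medians were 0.23 and 0.15 without POR-null control array 3. Exact permutation of list means, 6 arrays against 6, gave p = 0.0195 and p = 0.0173 (0.39 for both after adjustment over the lists).

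Another 7 lists passed in the genotype average with the preset correlation, each with an adjusted p of at least 0.785 with an estimated correlation. The medians were -0.11 for fatty acid oxidation genes (camera adjusted p = 2.71e-04), with Ppara at -0.30, 0.10 for interferon response genes (7.88e-04), -0.05 for oxidative phosphorylation genes (9.33e-04), -0.13 for NRF2 targets (0.0113), 0.08 for macrophage genes (0.0113), -0.09 for conjugating enzymes (0.0179) and 0.20 for smooth muscle genes (0.0373). Without wild type control array 2 the oxidation, phosphorylation, NRF2, macrophage and smooth muscle calls were lost, the conjugating call too, and without array 3 the interferon call (n = 6 arrays per genotype). The smooth muscle median fell slightly below 0 in at least 1 fit with a single array left out. In all, 9 of 40 lists passed, with 19 at most when wild type control array 1 was left out and 3 at least when POR-null quercetin array 3 was left out. By fry and with an estimated correlation 0 lists passed (smallest adjusted p = 0.456 by fry).

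Averaged over both genotypes, quercetin went with 0.53 (SE 0.10) in Plbd1, 0.19 in Rsrc1, -0.33 (SE 0.08) in Kdelr2, 0.35 in Hnrnpdl (0.05 to 0.23 in its other probe sets) and -0.31 (SE 0.07) in Errfi1, an inhibitor of EGFR signalling (6 arrays per diet). Of 22626 probe sets 0 passed by limma (adjusted p = 0.998 for each), and 735 (3.25%) had an unadjusted p under 0.05. Glycolysis and hypoxia genes were lower in 20 of 20 cases (median -0.10), with Hk2 at -0.31 (SE 0.11) and Ldha at -0.16 (SE 0.06). Immediate early genes were lower in 14 of 20 (median -0.10), with Atf3 at -0.32 (SE 0.08), Btg2 at -0.34 (SE 0.08), Egr1 at -0.39 (SE 0.11) and Fos at -0.38 (SE 0.15), and endoplasmic reticulum stress genes in 22 of 24 (median -0.11). The camera adjusted p were 1.16e-05, 6.14e-05 and 1.77e-07, and 0.347 for each with an estimated correlation; over the list alone 0, 3 and 0 passed, and 0 over all genes. Exact permutation of list means gave p = 0.0303, 0.0433 and 0.0519, and p = 0.0411 for the aryl hydrocarbon receptor targets (list mean difference -0.079), with 0.519 after adjustment over the lists for each. The glycolysis median was -0.05 without POR-null control array 2 and the stress median -0.17 without POR-null control array 3, and none of the 3 calls was lost.

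Smooth muscle genes had a median of 0.87 in the quercetin average, with Tagln at 1.62 (SE 0.55) and 16 of 16 higher, and 0.45 without wild type quercetin array 3 (6 arrays per diet). Fibroblast genes had 0.27, heat shock genes -0.17, with Hspa1b at -0.81 (SE 0.26), MHC class II genes 0.21, T and NK cell genes 0.05, fatty acid oxidation genes -0.05 and oxidative phosphorylation genes -0.04. The camera adjusted p were 8.18e-13, 1.69e-05, 7.61e-04, 0.0283, 0.0134, 0.0314 and 0.00272 in this order, and 0.409 for smooth muscle and 0.86 for the other 6 with an estimated correlation. The calls of these 6 lists were lost with some array left out, for instance the fibroblast call without POR-null control array 3 and the heat shock call without POR-null control array 2. In all, 10 of 40 lists passed, from 6 without wild type control array 2 to 20 without wild type control array 1, and 0 by fry (smallest adjusted p = 0.521) or exact permutation of list means.

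The interaction compares the quercetin difference of POR-null mice with that of wild type mice. For Ccn3 it was 3.20 (SE 0.50, 12 arrays), for Deptor 0.86 (SE 0.18, and 0.35 and 0.08 in its other probe sets), for Sdc4 -2.75 (SE 0.56, and 0.32 in its other probe set), for Gas5 -0.93 (SE 0.20) and for Dync1h1 -0.54 (SE 0.12). By limma 0 of 22626 probe sets passed (adjusted p = 0.45 for Ccn3 and 0.998 for the other 4), and 1073 (4.74%) had an unadjusted p under 0.05. Ccn3 passed without wild type quercetin array 1 (3.66, adjusted p = 0.0107), the array of its group with the highest Ccn3. The quercetin differences of the genotypes correlated at -0.325 over genes (Spearman -0.093, 47.1% of the same sign), and 97 of 100 other splits of the arrays gave a correlation at least as high. The genotype differences on the diets correlated at -0.309 (Spearman -0.038, 48.4% of the same sign), and 99 of 100 splits were as high. A negative correlation is thus at the low end of what other splits gave, from -0.39 to 0.39 and from -0.358 to 0.387. By camera 16 of 40 lists passed in the interaction (7 higher, 9 lower), and 0 with an estimated correlation (smallest adjusted p = 0.416) or by fry (0.539). Leaving out 1 array gave between 13 and 23 lists.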

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

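Of the tests used here, those on the smooth muscle list, on the acinar list, on covariates for tissue mix and on recovery with them were chosen only after results were seen. Of 40 gene lists 16 passed the interaction test of camera with the preset correlation, so their quercetin difference was unlike in the genotypes by that test alone, and 0 passed with an estimated correlation (smallest adjusted p = 0.416). The POR-null minus wild type difference in log2 change was taken for each gene, and its median over the list is given here. Immune genes gave -0.86 for B and plasma cells, -1.36 for MHC class II, -0.37 for macrophages and -0.16 for T and NK cells. Stromal genes gave -0.74 for fibroblasts, -1.24 for smooth muscle and -0.17 for endothelium. Pancreatic acinar genes gave 2.58 and small intestine genes 0.85. Xenobiotic genes gave 0.24 for conjugating enzymes, 0.19 for NRF2 targets and 0.45 for metallothioneins. Fatty acid oxidation genes gave 0.12, glycolysis genes -0.14, epithelial defence genes -0.12 and enteroendocrine genes 0.14.

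With an estimated correlation the adjusted p of these lists was 0.416, or 0.611 for fatty acid oxidation genes, and by fry it was at least 0.539. Over the list alone 6 B and plasma cell, 6 MHC class II and 1 acinar gene passed in the interaction, and 0 over all genes. Without wild type quercetin array 3 the smooth muscle value was -0.56, without wild type control array 3 the fibroblast value was -0.42, and without wild type control array 1 the small intestine value was 0.44. Of the 16 calls 8 were lost with some array left out, among them those of endothelial genes (-0.11 without POR-null quercetin array 2), fatty acid oxidation genes (0.04 without wild type control array 2), epithelial defence genes (-0.04 without wild type quercetin array 3) and enteroendocrine genes (0.06 without POR-null control array 1). The acinar value was 1.54 without POR-null quercetin array 2. With the smooth muscle, B and plasma cell and acinar means as covariates, those lists were left out of the test, so their calls could not be kept. Of the lists that remained 3 passed, and 0 with an estimated correlation. The direction by camera turned for fatty acid oxidation, macrophage, fibroblast and endothelial genes.

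Splits of the arrays, with the real groups counted among them, give a measure of what structure unrelated to the factor compared can do. In the interaction 15 of 100 splits called at least as many lists as the 16 of the real groups, with up to 25. For the quercetin average 61 of 100 splits reached the real 10 lists, with up to 23, and for the genotype average 68 of 100 reached the real 9, with up to 23. Arrays were drawn within each genotype for the interaction and the quercetin average, and within each diet for the genotype average. Groups drawn without regard to diet in the former, or to genotype in the latter, may thus be enough for these numbers of lists. In the simple contrasts, with only 10 splits, 4 reached the 16 lists of quercetin in wild type (highest 20), 7 the 10 lists of quercetin in POR-null (highest 15), 2 the 19 lists of genotype on control diet (highest 19) and 10 the 6 lists of genotype on quercetin diet (highest 19). These 10 splits are too few for a share under 0.05. A split with 19 lists where the real groups gave 6 may reflect a structure of the samples across the groups or the preset correlation, which lies below that of the lists, and no test here parts the one from the other.

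For single probe sets the real number was 0 in each contrast, so that every split reached it, 10 of 10 in each simple contrast and 100 of 100 in the interaction and in both averages. The highest numbers in other splits were 8 for quercetin in wild type, 3 for quercetin in POR-null, 2 for genotype on control diet, 0 for genotype on quercetin diet, 7 for the interaction, 4 for the quercetin average and 31 for the genotype average. A split with 31 calls where the genotypes gave 0 may point to a structure of the samples, which no test here separated from chance calls among genes that move together. Differences in tissue mix could hide changes between groups, yet with 3 list means as covariates the largest number in a simple contrast was still 0. That fit recovered between 69% and 89.1% of 2-fold changes put into 200 probe sets, against 93.2% to 95.5% without the covariates. The covariates thus made the fit less sensitive. Either fit would have found most changes of that size and number, so such hidden changes are argued against, while smaller or fewer ones stay open.

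The smooth muscle and matrix genes that were higher in wild type mice on quercetin could come from unequal carry-over of the tissue under the epithelium, as the labels state that the layer was scraped off. The SD of the smooth muscle list mean was 1.38 over the 3 wild type quercetin arrays, against a difference of 1.53 (SE 0.64 from the list mean) between the diets, and carry-over stays open. A uniform loss of epithelial cells, which would raise the genes of other cell types alike, cannot be told apart from carry-over, as the smooth muscle list mean rose by 0.86 more than that of the fibroblast and matrix genes with an SE over arrays of 0.55, carried mostly by array 3 at 1.73. An action of quercetin alike in both genotypes cannot be told apart from a difference, as the list means gave 0.25 (SE 0.64) in POR-null mice and an interaction of -1.28 (SE 0.90).

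Acinar genes were high in wild type control arrays 1 and 2 and in POR-null quercetin array 2, with Cela2a, an elastase looked up after values were seen, at 8.35, 6.90 and 9.81 and a median over 12 arrays of 4.30. Wild type quercetin array 2 came next, with a list mean of 7.14 against 7.25 in wild type control array 2 and with Cela2a at 5.98. The 14 genes correlated with one another at a mean of 0.74 over a range of 3.58 in the list mean, so that pancreatic tissue attached to some colon samples stays open. In the other 9 arrays 5 of the 14 genes still lay above the array median, and Pnliprp2 went the other way on control diet, so the list does not stand for pancreas alone.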

How the results depend on the processing

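Leaving out 3 arrays, the covariates and exact permutation of list means were chosen only after results were seen. Signal over background was not measured apart from the deposited values, so that small differences in genes near the lowest signal are compressed. Log2(value + 1) and log2(value + 64) were planned for linear values and not run, as the values were log2 already. Quantile normalization, equal medians, leaving out dim probe sets, trend=FALSE, robust=TRUE, 1 probe set per gene and an adjusted p under 0.1 left all numbers of probe sets at 0. Among the list counts under quantile normalization, without dim probe sets or with the probe set of the largest variance, the furthest was 14 lists without dim probe sets for genotype on control diet, against 19.

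Array weights gave 2 probe sets for quercetin in wild type and 399 for genotype on control diet where equal weights gave 0. Fitting only the 6 arrays of the contrast gave 1 for genotype on quercetin diet, which was Sdc4. With the replicate number as a block there was 1 for genotype on quercetin diet, Sdc4 at adjusted p = 0.0467 against 0.926 without the block, and the pairing of arrays by number that such a block assumes is not stated in the labels. Residuals of arrays with the same number correlated at a median of 0.041 over 18 pairs, with 6 pairs above 0.1. For different numbers the median was -0.022. Among arrays of the other groups, of which 1 in 3 has the same number, 8 of 12 arrays matched their own number best. This is a hint from the data and not from the design. The cause was not tested for these differences.

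With an estimated correlation 0 gene lists passed in each of the 7 contrasts, quercetin in wild type, quercetin in POR-null, genotype on control diet, genotype on quercetin diet, interaction, quercetin average and genotype average. By fry 0 passed in each of them as well, and exact permutation of list means gave 0 for the quercetin average and 0 for the genotype average. Without the 3 arrays of most acinar signal there were 17 lists for the quercetin average, 15 for the genotype average and 1 probe set for genotype on control diet. Values of the other sign then were 0.03 for Cyp1a1 (quercetin in POR-null), and for acinar genes 0.38 (quercetin in wild type) and 0.02 (genotype on control diet). The 3 arrays were chosen by the acinar list, so its values follow from that choice.

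With tissue mix covariates there were 4 lists for quercetin in wild type, 9 for genotype on control diet, 10 for genotype on quercetin diet, 3 for the interaction and 14 for the genotype average. The lists used as covariates were left out of these tests. With an estimated correlation these and all other contrasts had 0. The direction by camera, which is relative to all genes, turned for lists with medians, for quercetin in wild type, of 0.09 for ion and water transport, 0.01 for fibroblast and -0.06 for endothelial genes. They were 0.02 for macrophage genes (quercetin in POR-null), -0.03 for fibroblast and -0.02 for endothelial genes (genotype on control diet), and 0.11 for fibroblast genes (genotype on quercetin diet, adjusted p = 0.0185, and 0.86 with an estimated correlation). In the interaction they were -0.09 for fatty acid oxidation, 0.00 for macrophage, 0.14 for fibroblast and 0.14 for endothelial genes.

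Leaving out each array in turn gave 0 to 3 probe sets for quercetin in wild type, 0 to 1 for quercetin in POR-null, 0 to 41 for genotype on control diet, 0 to 1 for genotype on quercetin diet, 0 to 1 for the interaction, 0 to 1 for the quercetin average and 0 to 2 for the genotype average. Numbers of lists ran from 12 to 19, 8 to 16, 15 to 22, 5 to 12, 13 to 23, 6 to 20 and 3 to 19 in the same order. The correlation of quercetin responses ran from -0.37 to -0.171 and that of genotype differences from -0.374 to -0.13. Cyp1a1 ran from -0.01 to 0.11 for quercetin in wild type and from -0.12 to 0.06 in POR-null. The smooth muscle median ran from -0.05 to 0.49 for the genotype average and the cell cycle median from -0.23 to 0.00 for genotype on quercetin diet. The cause was not tested.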

Other observations

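The test on wild type control arrays 2 and 3, the exact permutation of list means and the test on neighbouring genes were chosen only after results were seen. Sterol synthesis needs electrons from POR at squalene epoxidase and at lanosterol demethylation, and livers without POR are known to raise the genes of this route, as sterols that shut it down are lacking. The line deletes the gene in hepatocytes, so its colon is expected to keep the gene, which is not analysed here. The liver route is thus background only, and no mechanism in the colon was tested.

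The list mean of the cholesterol synthesis genes was higher in POR-null mice by 0.214 (SE 0.081, ordinary fit of the list mean) over both diets, by 0.264 on control diet and by 0.164 on quercetin (SE 0.115 each). The difference over both diets was 0.207 (SE 0.085, 5 residual degrees of freedom) with the smooth muscle, B and plasma cell and acinar list means as covariates. This argues against these 3 lists as its source, while other parts of the tissue mix were not in the fit and stay open. Exact permutation of 6 against 6 arrays gave p = 0.0195, which is consistent with an effect of genotype, though it came to 0.39 after adjustment over the lists. Wild type control arrays 2 and 3 had the lowest means, 7.82 and 7.72, and cannot be told apart from genotype as a source. The quercetin diet, which does not use them, gave 0.164 without reaching 2 of its SE. Its arrays only just did not overlap (8.071 against 8.051, 10% by chance). On control diet the groups overlapped, with wild type array 1 at 8.1 and POR-null array 3 at 7.988.

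The lower Ccn3 and Deptor in wild type mice on quercetin lie near each other in the genome, with 3 protein-coding genes between them. Ccn3 differed by -1.90 (SE 0.63, 5 residual degrees of freedom) with the smooth muscle, B and plasma cell and acinar list means as covariates. The ordinary fit with no covariates gave -2.64 (SE 0.44). This argues against these 3 lists as the whole source, while other parts of the tissue mix were not in the fit and stay open. A chromosome segment that differs between the pools cannot be told apart from other sources. The 6 measured neighbours within 1 Mb correlated with Ccn3 at a median absolute value of 0.12 where all genes gave 0.24, at percentile 7 of 10000 random sets, yet Mal2 reached 0.46 with a difference of -0.36, and Mtbp 0.37. Whether quercetin lowers Ccn3 in wild type mice stays open as well. The adjusted p by limma was 0.119 over 12 arrays, and Ccn3 passed with array weights (0.0195). It also passed without wild type quercetin array 1 (0.00264), the array of its group with the highest Ccn3 (5.47 against 4.42 and 3.72). Leaving that array out enlarges the difference, so this fit is no separate support.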
